A study of Mus musculus with 5 samples.

How the data were processed

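The data are whole-tumour RNA profiles of 5 mouse gliomas, 3 mutIDH1 and 2 wtIDH1, each measured as 1 biotin-labelled sample on an Illumina BeadArray. Groups and sample numbers were taken from the sample titles. The deposited values used here are log2 signals of 45281 probes per array. Per the submitters' processing notes the authors used limma, with no version given; which of its background and normalization steps was applied is not given in the sources used here. The values themselves show that all 5 arrays share 1 distribution, as after quantile normalization (array medians differ by at most 0.00069), run from 6.91 to 15.06, and have a lowest linear signal of 120.2, so background had not been subtracted to 0. Without background subtraction, differences of dim genes are compressed towards 0. Quantile normalization also removes any difference in total RNA signal between the tumours.

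A table of non-normalized signals and detection p-values was also given. Its 10 columns of per-sample values carry names that match no single sample's labels and were not used, because columns were not matched to samples by order or by values. The planned background correction with negative controls (neqc) and filter on detection p therefore gave way to the fallback fixed for a table without detection p, that of leaving out the dimmest 20% of probes. Its normexp and quantile steps were not repeated on values that were already normalized, and normexp was run as an alternative instead.

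Probes were named through the platform annotation. Of the probes, 34885 had 1 gene symbol, 18 had several and were named by none, and 10378 were unnamed here; 34807 gene identifiers matched the RefSeq table of assembly GRCm38.p6, which updated symbols and gave the order of neighbouring genes. No coordinates were used, since no genome build is named for the array. Probes with a mean under 7.23 (the dimmest 20%) were left out, 29160 named probes remained, and each gene was represented by its probe with the highest mean, which left 16917 genes. Of 120 changed genes with more than 1 probe, 94 had all probes on the same side of 0. A background level was estimated as the mode of the signals, 7.24, plus 3 times the spread below it (0.0885), which gave 7.51. A gene at or under it on every array of a group has only a bound there, and its fold is given as "at least": the mean of the bright group against the higher of the background level and the dim signal on each array. On all arrays 5020 tested genes lay at or under this level, and 13 changed genes did so in mutIDH1 and 3 in wtIDH1.

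Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, group as the only term, all 5 samples), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. There were 3 residual degrees of freedom and 2.50 prior degrees of freedom. Changes are mutIDH1 minus wtIDH1 on the log2 scale with the moderated standard error, on 3 and 2 samples. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists with at least 5 measured genes; a list of sex-linked genes had 4 and was only read out per sample. The lists named 827 genes, of which 715 were measured; the others were not analysed here. The score of a list is the mean over its genes of the log2 signal centred on the gene's mean. Each list's genes were also adjusted over the list alone. Lists share members, so they are not independent of each other.

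The tests, the lists and the rule for naming genes were fixed before the data were examined. The rule takes the genes of the tumour model whatever their value, the 10 largest rises and 10 largest falls among changed genes with non-overlapping groups, and up to 4 members with the smallest p of each list that passed or that holds immune or cell type markers; predicted and clone-named genes (1 among the changed) were counted only. As applied, the rule was widened to up to 4 members with the smallest p from every list tested. Genes named outside the rule are said to be chosen after their values were seen, or serve as named members of a count of 6 or fewer.

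Simulated data had 16917 genes, each with its pooled real spread used for both groups. The test recovered 60 of 100 genes planted with a log2 change of 1 and 100 of 100 with a change of 2, with 5 false calls. The real wtIDH1 samples differed more (SD of their difference 0.40, against 0.18 to 0.26 between mutIDH1 samples). These counts may therefore not hold for the real data. A shift of −0.5 planted in the extracellular matrix list was called, and 0 of the 31 other lists were. Genes were simulated independently of each other, so this cannot show how often camera calls lists of correlated genes. In the real data the estimated correlation ran from −0.057 within the B and plasma cell list to 0.64 within the neuron list. Within the matrix list it was −0.019. Alternatives covered the filter on dim probes, the treatment of several probes per gene, variance moderation, array weights, a block by sample number, leaving out each sample, thresholds, a test without moderation, the correlation and kind of list test, and lists without shared genes. Added after the data were seen were normexp with an offset of 50, stricter filters on dim probes, centring on genes above background, cyclic loess and sex as a covariate. Array batches are not given in the labels and were not tested.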

Results

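Gene expression was measured in 5 mouse gliomas on Illumina BeadArrays, 3 carrying mutant IDH1 (mutIDH1) and 2 carrying wild-type IDH1 (wtIDH1). The tumours were raised with the RCAS/tva system, in which DF1 cells, a chicken fibroblast line, release avian retroviruses that can enter only mouse cells bearing the tva receptor. Mice without functional Ink4a/Arf, a tumour suppressor locus, received DF1 cells making PDGFa virus together with cells making virus for either form of IDH1 joined to shp53, by its name a short hairpin RNA against p53. IDH1 is the cytosolic isocitrate dehydrogenase, and its tumour-associated mutants produce the metabolite 2-hydroxyglutarate. By its title the series asks how mutant IDH1 acts on the immune cells associated with gliomas. RNA came from whole tumour tissue, so each value covers tumour cells together with vessels, blood and immune cells. The labels give each sample its own tumour code, and the 5 samples were taken as separate tumours.

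Of 45281 probes on each array, between 18950 and 18960 lay above the estimated background level of 7.51 on the log2 scale, and 16917 named genes were tested. The small number of arrays limits the precision of every value. The 3 mutIDH1 samples resembled each other (Pearson r between 0.988 and 0.994 over the 16917 tested genes, which are not independent). The 2 wtIDH1 samples differed more from each other (r = 0.971). Between the groups r ran from 0.969 to 0.980, so each wtIDH1 sample was closer to some mutIDH1 samples than to the other wtIDH1 sample. The first principal component (45.4% of the variance) set wtIDH1 sample 1 apart and the second (34.7%) set wtIDH1 sample 2 apart. Xist, the transcript of the inactive X chromosome, was at 10.42 in mutIDH1 sample 1 and 10.44 in wtIDH1 sample 1, and between 7.13 and 7.33 in the others, where the Y-linked gene Eif2s3y was between 9.64 and 10.52. Each group therefore held at least 1 female and 1 male tumour.

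Among the genes named by the tumour model, only Pdgfa, the growth factor gene of the same name as the delivered virus, differed by the test. Pdgfa fell by 0.69 ± 0.07 (log2, SE) in mutIDH1, from 11.53 ± 0.01 (SD, n = 2) in wtIDH1 to 10.83 ± 0.01 (SD, n = 3), with a limma adjusted p of 0.0227. Idh1 was at 11.08, 10.73 and 10.94 in the mutIDH1 samples and at 11.02 and 10.47 in the wtIDH1 samples, a difference of 0.17 ± 0.19 (adjusted p = 0.783). Whether the probes read the delivered IDH1 and PDGFa is not given in the sources used here, so these values do not check the labels. Idh2, the mitochondrial isoform, stood at −0.76 ± 0.12 (adjusted p = 0.0596), and Pdgfra, the receptor of PDGFa, at 0.37 ± 0.12 (adjusted p = 0.246), where its second probe had the opposite sign. Cdkn2a, the Ink4a/Arf gene, gave signal above background in both groups (9.49 and 9.92, difference −0.44 ± 0.25, adjusted p = 0.539); where its probe lies relative to the deletion is not known here. Cdkn2b stood at 0.18 ± 0.35 (adjusted p = 0.895), and Trp53 was not analysed here. Leaving out wtIDH1 sample 2 turned Idh1 to −0.10 and Cdkn2b to −0.20, and leaving out mutIDH1 sample 3 turned Cdkn2b to −0.048. Over the samples left out, Cdkn2a ranged from −0.74 to −0.14. Pdgfra was 0.20 without wtIDH1 sample 2 and 0.18 with the mean of its probes.

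The comparison of mutIDH1 with wtIDH1 gliomas asks which transcripts of the tumour and its surroundings depend on the form of IDH1. In mutIDH1 gliomas, 152 genes fell and 76 rose, and at least a 2-fold change was met by 78 of those that fell and 17 of those that rose. The 10 steepest falls included 3 Hoxa genes and 2 matrix metalloproteinases, and among genes that passed, the largest rise, that of Liph, was smaller than all of them. Hoxa5 and Hoxa7, homeobox genes that set position along the body axis, were at or under background in all 3 mutIDH1 samples and were at least 10.9-fold and at least 10.6-fold higher in wtIDH1 (adjusted p = 0.00607 and 0.00199). Hoxa2 and Skap2, an adaptor protein of leukocyte signalling, fell by 2.36 ± 0.18 and 2.31 ± 0.25, and En1, a midbrain and hindbrain homeobox gene, fell by 2.33 ± 0.08.

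Other steep falls were in the matrix metalloproteinases Mmp13 (−2.62 ± 0.25) and Mmp9 (−2.59 ± 0.33), in Mgp, an inhibitor of calcification (−2.54 ± 0.14), in Capn6 (−2.52 ± 0.16) and in Ms4a7, a macrophage membrane protein (−2.51 ± 0.30). For Mmp13 only 2 of 3 probes had this sign, and the mean of its probes gave −1.05 (adjusted p = 0.0548). The largest rises were in Liph, a phospholipase (1.81 ± 0.23), Ccnd2, cyclin D2 of the transition into S phase (1.72 ± 0.23), Thsd7b (1.67 ± 0.08), Kcnv1, a potassium channel subunit (1.56 ± 0.18), and Cxcl13, a chemokine that attracts B cells (1.53 ± 0.20). Sall3, a zinc finger transcription factor, rose by 1.49 ± 0.14, Brinp1 by 1.46 ± 0.21, Hs3st3a1, a heparan sulphate sulphotransferase, by 1.38 ± 0.14, Bdnf, a neurotrophin, by 1.36 ± 0.14 and Inka2 by 1.35 ± 0.08. Their adjusted p ranged from 0.00709 for Thsd7b to 0.0478 for Brinp1. With the mean of its probes Bdnf gave 0.34 (adjusted p = 0.105), and Ccnd2 (1.13), Thsd7b (0.85), Kcnv1 (0.79) and Ms4a7 (−1.47) gave smaller changes that still passed.

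**Figure D1:**
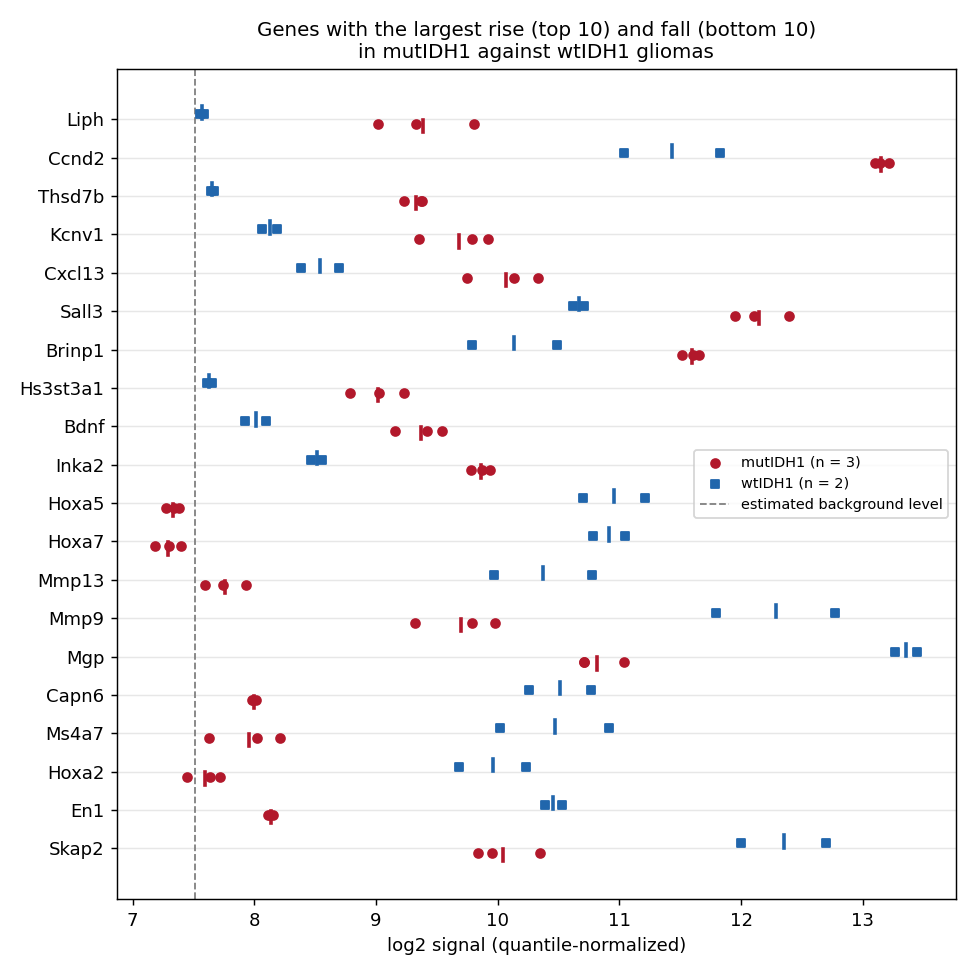
Log2 signal of the 10 genes with the largest rise and the 10 with the largest fall (vertical axis) in each of the 3 mutIDH1 samples (red circles) and the 2 wtIDH1 samples (blue squares); short bars are group means and the dashed line is the background level of 7.51. The groups do not overlap for any of these genes, as their selection required, and Hoxa5 and Hoxa7 lie under the line in all mutIDH1 samples.

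In the test behind these counts, limma with Benjamini-Hochberg adjustment over 16917 genes at 0.05, all 228 changed genes had groups that did not overlap. Of all tested genes 30.6% showed this, and chance gives 20%. With so few samples a gene with overlapping groups can hardly reach the threshold, so the absence of overlap among the 228 is no support of its own. Leaving out mutIDH1 sample 1 left 14 genes, leaving out mutIDH1 sample 2 or 3 left 0 (1747 and 1849 at an unadjusted p under 0.05, against 2429 with all samples), and leaving out wtIDH1 sample 2 gave 479, so every single-gene call made over all genes was lost without either of these mutIDH1 samples, while the changes of the called genes picked by the naming rule stayed between 0.883 and 1.09 times their value. Without wtIDH1 sample 1 the adjusted p was 0.0595 for Liph and 0.0547 for Kcnv1, and without wtIDH1 sample 2 it was 0.0510 for Cxcl13. With sex as a covariate 59 genes passed, and 29 of the genes picked by the naming rule lost their call (adjusted p from 0.0517 to 0.0946) with changes between 0.966 and 1.04 times those without it: Pdgfa, Liph, Ccnd2, Cxcl13, Sall3, Brinp1, Ms4a7, Vwf, Emcn, Slc2a1, Egfl7, Mrc1, Egln3, Pdk1, Pdgfrb, Col3a1, Anxa2, Lgals3, S100a9, Clec4d, Fcgr2b, Ifi30, Taldo1, Pf4, Ccl9, Fpr2, Ncan, Ier3 and Aqp1. Brinp1 also lost its call with cyclic loess. Of the genes given below that did not pass, Vegfa, Rsad2, Alas2, Ctss, Sox9 and Prf1 passed without wtIDH1 sample 1. Rsad2, Tnfaip3, Vcam1 and Sox9 passed without wtIDH1 sample 2. In those fits the spread came from the mutIDH1 samples alone, so passing there is no support. With trended and robust moderation Vegfa, Rsad2, Ifitm3, Tnfaip3, Il1b, Pecam1, Kcnc1 and Fcrls passed, as did Idh2.

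Of 32 gene lists tested together with camera, limma's test of a list against all other genes, 16 were lower in mutIDH1 and 0 were higher. Among the lists that passed, the median shift was largest for red blood cell markers, then extracellular matrix, endothelial markers, hypoxia and glycolysis, and mural cells, while T cell, B cell, dendritic cell and MHC class I lists did not pass. These calls use a preset correlation of 0.01 between genes. With an estimated correlation 0 lists passed, and fry, limma's rotation test of a list on its own, called 11. The estimate lay above the preset for some called lists (endothelial 0.23, interferon 0.31) and below it for others (matrix −0.019, mural −0.0067). A higher correlation therefore does not account for the loss of the matrix and mural calls, whose cause was not tested. Of the 16 lists, fry did not call red blood cells, MHC class II, interferon, inflammatory cytokines, chemokine ligands or cell cycle. The same camera test called 18 lists when mutIDH1 samples 1 and 2 were set against the other 3 samples. That division keeps both wtIDH1 samples together, and the divisions that separated them called between 5 and 11 lists.

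**Figure D2:**
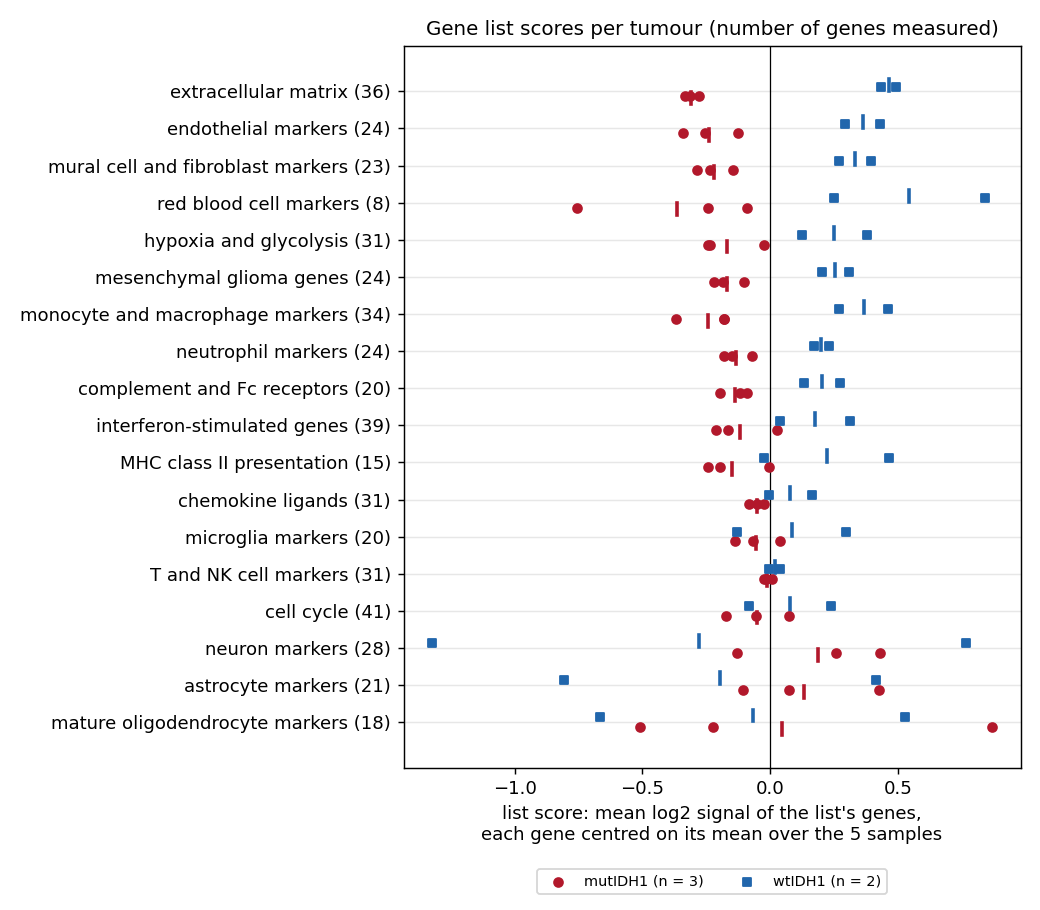
Scores of 18 gene lists (vertical axis, with the number of genes measured) in the 3 mutIDH1 samples (red circles) and the 2 wtIDH1 samples (blue squares); a score is the mean log2 signal of the list's genes after each gene is centred on its mean over the 5 samples, and short bars are group means. The extracellular matrix score was −0.31 ± 0.03 (SD) in mutIDH1 and 0.46 ± 0.04 in wtIDH1, while the neuron score differed most between the 2 wtIDH1 samples (−1.33 and 0.77).

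Genes of the extracellular matrix were lower in mutIDH1 gliomas, with a median log2 change of −0.81 over 36 measured members. 10 of them fell when adjusted over all genes, among them the collagens Col8a1 (−1.74 ± 0.09), Col18a1 (−1.47 ± 0.10) and Col1a1 (−1.53 ± 0.11) and the collagen crosslinking enzyme Lox (−2.18 ± 0.13). Ncan, neurocan of the brain's own matrix, rose by 0.66 ± 0.08. Adjusted over the list alone, 26 fell and 2 rose. For Col18a1 2 of 3 probes had this sign, and their mean gave −0.68, which still passed. The camera adjusted p was 1.29e-18, and adjusted p = 0.0561 with an estimated correlation. For Ncan the adjusted p was 0.0663 without wtIDH1 sample 1 and just above the threshold without wtIDH1 sample 2, and the call was lost with normexp too.

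Vessel genes moved the same way. Among 24 endothelial markers (median −0.65), 6 fell over all genes and 14 adjusted over the list alone, including Vwf, the platelet-binding factor of endothelial cells (−1.34 ± 0.14), Emcn, a sialomucin of veins and capillaries (−1.26 ± 0.13), and Slc2a1, the glucose transporter of the blood-brain barrier (−0.77 ± 0.08). Among 23 mural cell and fibroblast markers (median −0.39), 4 fell over all genes, and 12 fell and 1 rose adjusted over the list alone; Acta2, smooth muscle actin, fell by 2.19 ± 0.18 and Pdgfrb, the receptor that marks pericytes, by 0.68 ± 0.07. With sex as a covariate Vwf, Emcn, Slc2a1 and Pdgfrb lost their call at much the same change (−1.36, −1.25, −0.76 and −0.69). The mean of its probes gave −1.46 for Acta2, which still passed. The camera adjusted p was 5.26e-13 and 1.92e-08, and adjusted p = 0.174 and 0.116 with an estimated correlation. Red blood cell markers, a measure of blood in the tissue, were lower as well, with a median of −1.10 over 8 genes, of which 0 fell over all genes by limma (3 adjusted over the list alone; Alas2 −1.71 ± 0.38, adjusted p = 0.123). That list had a camera adjusted p of 0.000403, and adjusted p = 0.362 with an estimated correlation; its globin genes are near-identical copies whose probes are uncertain.

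Hypoxia and glycolysis genes had a median change of −0.47 over 31 members, of which 3 fell over all genes, and 18 fell and 1 rose adjusted over the list alone. They were Slc2a1 (also on the endothelial list), Egln3, a prolyl hydroxylase that acts on HIF (−1.21 ± 0.11), and Pdk1, the kinase that restrains pyruvate dehydrogenase (−1.01 ± 0.11, and adjusted p = 0.0679 with the mean of its probes). For Egln3 that mean gave −0.46, which still passed. Vegfa stood at −0.99 ± 0.16 (adjusted p = 0.0642). The camera adjusted p was 3.02e-10, and adjusted p = 0.211 with an estimated correlation. Of 24 mesenchymal glioma genes (median −0.24), 5 fell over all genes, among them Emp1 (−1.54 ± 0.10), Tgfbi (−1.68 ± 0.16) and the annexin Anxa2 (−1.50 ± 0.14); adjusted over the list alone 11 fell and 2 rose (Anxa2 −0.93 with the mean of its probes, which still passed; camera adjusted p = 1.00e-06, and adjusted p = 0.139 with an estimated correlation).

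Myeloid markers fell in part. Of 34 monocyte and macrophage markers, 6 fell over all genes and 12 adjusted over the list alone, among them Plac8 (−1.37 ± 0.08), the mannose receptor Mrc1 (−1.35 ± 0.12), the transglutaminase subunit F13a1 (−1.21 ± 0.13) and Ms4a7. The list's median was −0.22 and its mean −0.61, and without wtIDH1 sample 1 the median was −0.47. Of 24 neutrophil markers (median −0.10, mean −0.33), 5 fell over all genes and 5 adjusted over the list alone: S100a8 (−1.80 ± 0.15), S100a9 (at least 2.27-fold lower), Clec4d (at least 1.58-fold lower), Fpr2 and Mmp9, a protease that other cells also make. Without wtIDH1 sample 1 the adjusted p was 0.0518 for Clec4d and 0.0861 for Fpr2, while normexp took Fpr2 from −0.63 to −0.99. The camera adjusted p was 1.19e-10 for monocytes and macrophages and 3.44e-05 for neutrophils, and adjusted p = 0.139 for both with an estimated correlation. Microglia markers did not pass (20 genes, median −0.050, camera adjusted p = 0.181), with Fcrls at −0.90 ± 0.20 and Aif1 at −0.61 ± 0.16. That list passed without wtIDH1 sample 1 (−0.33, adjusted p = 0.000169) and without mutIDH1 sample 2 (−0.13, adjusted p = 0.0463), and its median turned to 0.083 without wtIDH1 sample 2 (adjusted p = 0.312).

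Lists of innate effector pathways were lower too by camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.174 for complement and Fc receptors, 0.362 for interferon and 0.263 for inflammatory cytokines). Of 20 complement and Fc receptor genes (median −0.25), 3 fell over all genes and 3 adjusted over the list alone: Serping1, the inhibitor of the C1 complex (−1.85 ± 0.21), C4b, a complement component whose near-identical copy C4a leaves it uncertain (−1.26 ± 0.09), and Fcgr2b, the inhibitory Fc receptor (−0.98 ± 0.09). For Fcgr2b 2 of 3 probes had this sign, and the mean of the probes gave −0.50 for it and −0.77 for C4b, both of which still passed. Of 39 interferon-stimulated genes (median −0.21), 0 fell over all genes by limma and 8 adjusted over the list alone, with Rsad2, an antiviral enzyme, at −1.42 ± 0.22 (adjusted p = 0.0554) and Ifitm3 at −0.99 ± 0.18 (adjusted p = 0.0823). Of 34 inflammatory cytokines and NF-kB targets (median −0.15), 0 fell over all genes by limma and 6 adjusted over the list alone, with Tnfaip3 at −0.64 ± 0.10 (adjusted p = 0.0522) and Il1b at −0.54 ± 0.10 (adjusted p = 0.0830). The camera adjusted p at the preset correlation was 4.16e-05, 4.30e-07 and 8.02e-05, and fry called only the first of the 3 lists. The interferon median was −0.12 without mutIDH1 sample 2, −0.13 without wtIDH1 sample 1 and −0.32 without wtIDH1 sample 2, and the complement median was −0.38 and −0.14 without wtIDH1 sample 1 and 2.

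Antigen presentation was covered by 2 lists, of which 1 passed. Of 15 MHC class II presentation genes (median −0.33), Ifi30, a lysosomal thiol reductase, was the 1 that fell over all genes (−0.83 ± 0.08), and 2 fell adjusted over the list alone. With the mean of its probes Ifi30 gave −0.54 and still passed. Ctss, the protease that cleaves the invariant chain, stood at −0.68 ± 0.28 (adjusted p = 0.360), or −1.17 without wtIDH1 sample 1 (adjusted p = 0.0190) and −0.19 without wtIDH1 sample 2. The list's camera adjusted p was 0.000860, and adjusted p = 0.362 with an estimated correlation; it was 0.199 without wtIDH1 sample 2, where the median was −0.062, and the median was −0.20 without mutIDH1 sample 3. Among 21 MHC class I presentation genes 0 passed in limma, over all genes or over the list alone, the median was −0.039, and H2-T23 stood at −0.37 ± 0.21 (camera adjusted p = 0.399, but 0.0149 at −0.11 without mutIDH1 sample 1, and 0.478 at 0.090 without mutIDH1 sample 2). The difference between the classes was not tested.

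Chemokine genes moved in both directions. Of 31 chemokine ligands, Cxcl13 rose, Pf4, platelet factor 4, fell by 1.91 ± 0.25 and Ccl9, a ligand for myeloid cells, fell by 0.70 ± 0.10; adjusted over the list alone 4 fell and 1 rose. The median was −0.031, with a camera adjusted p of 0.0381, and adjusted p = 0.245 with an estimated correlation. That call was lost without mutIDH1 sample 1 (−0.048, adjusted p = 0.0966) and without wtIDH1 sample 2 (−0.028, adjusted p = 0.287), and the median was −0.069 without mutIDH1 sample 3 and −0.16 without wtIDH1 sample 1. It was also lost with no filter on dim probes, with only probes above background and with cyclic loess. Ccl9 had an adjusted p of 0.0672 without wtIDH1 sample 2, and Cxcl13 of 0.0510; Pf4 and Ccl9 lost their call with cyclic loess, and Ccl9 with array weights. Of 26 chemokine and chemoattractant receptors (median −0.046), Fpr2, a formyl peptide receptor, fell by 0.63 ± 0.09 both over all genes and adjusted over the list alone, a call over all genes that array weights and both stricter filters on dim probes ended. Cxcr4 stood at −0.49 ± 0.12 (adjusted p = 0.154), and camera gave an adjusted p of 0.0598, or 0.0282 without wtIDH1 sample 1; the list also passed with both stricter filters on dim probes (−0.25 and −0.31) and with fry. Of 16 leukocyte integrins and adhesion genes 0 passed over all genes by limma, and 3 fell and 1 rose adjusted over the list alone. Pecam1 stood at −0.76 ± 0.14 and Vcam1 at 0.74 ± 0.19. The mean of the probes gave −0.38 for Pecam1 and 0.21 for Vcam1, and Vcam1 was 0.46 without wtIDH1 sample 1. The camera adjusted p was 0.0373, and adjusted p = 0.245 with an estimated correlation; it was 0.0597 without mutIDH1 sample 1, 0.117 without wtIDH1 sample 1, and the call was lost without wtIDH1 sample 2 as well. It was also lost with no filter on dim probes, both stricter filters, every probe on its own and array weights, and held in 11 of 20 alternatives.

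Lymphocyte and dendritic cell markers showed no change past the test, and many lay near background. Of 31 T and NK cell markers, 19 were at or under background on all arrays and 0 passed in limma over all genes or over the list alone. Prf1, perforin, stood at −0.74 ± 0.22 (limma adjusted p = 0.211) and Cd8b1 at 0.20 ± 0.12. Without wtIDH1 sample 2 they were −0.38 and 0.38, and Cd8b1 was 0.013 without wtIDH1 sample 1. Of 16 B and plasma cell markers 7 and of 16 dendritic cell markers 8 were likewise at background, and 0 of either list passed. Their medians were −0.0090 for T and NK cells, −0.043 for B and plasma cells and 0.014 for dendritic cells, with camera adjusted p of 0.604, 0.505 and 0.596. The dendritic cell mean was −0.019, on the other side of 0 from its median, and its test pointed lower.

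Neural and glioma lineage lists did not pass, although single members changed. Of 22 genes of oligodendrocyte progenitors and the glioma lineage, Sox2, a transcription factor of neural stem cells, rose by 0.99 ± 0.08 (0.57 with the mean of its probes, which still passed) and Ncan by 0.66 ± 0.08, and adjusted over the list alone 5 rose and 4 fell. The list's median was 0.14 (camera adjusted p = 0.0903). Sox9, a transcription factor of astrocytes and neural stem cells, had the largest difference on the astrocyte list at 2.33 ± 0.34, with 12.93 ± 0.07 in mutIDH1 and 10.60 ± 0.86 in wtIDH1 (SD), and just missed the threshold (adjusted p = 0.0509). It passed in 8 of 17 alternatives, among them those without wtIDH1 sample 1 (change 1.72) and without wtIDH1 sample 2 (2.94). With 1 wtIDH1 sample left, the spread came from the mutIDH1 samples alone. The large spread between the wtIDH1 samples then dropped out, so passing in those fits is no support. In all, 0 of 21 astrocyte genes passed in limma and 2 rose adjusted over the list alone (median 0.22, camera adjusted p = 0.116). Among 28 neuron markers 0 passed in limma (median 0.39, camera adjusted p = 0.128), with Kcnc1 at 0.87 ± 0.16 (adjusted p = 0.0815). The neuron score was −1.33 in wtIDH1 sample 1 and 0.77 in wtIDH1 sample 2, so the neuron median was −0.39 without sample 1 (adjusted p = 2.81e-05) and 1.33 without sample 2 (adjusted p = 2.45e-13). The astrocyte median was −0.22 without wtIDH1 sample 1, 0.59 without wtIDH1 sample 2 (adjusted p = 2.16e-08) and 0.30 without mutIDH1 sample 3 (adjusted p = 0.0483). Mature oligodendrocyte markers (18 genes, median 0.14, but −0.20 without mutIDH1 sample 1 and −0.49 without wtIDH1 sample 1, camera adjusted p = 0.744, 0 passed) and ependymal and choroid plexus markers (8 genes, median 0.099, camera adjusted p = 0.543) did not pass, although the water channel Aqp1 of the second list fell by 2.01 ± 0.26, or by 1.33 with an adjusted p of 0.0541 with the mean of its probes.

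Metabolic and growth lists had small shifts. Of 20 NADPH and glutathione genes (median −0.16), Taldo1, an enzyme of the pentose phosphate pathway, fell by 0.67 ± 0.10, and 2 fell adjusted over the list alone (camera adjusted p = 0.000872, and adjusted p = 0.160 with an estimated correlation). Taldo1 had an adjusted p of 0.0889 without wtIDH1 sample 1 and 0.0607 without wtIDH1 sample 2, and lost its call with array weights, normexp and both stricter filters on dim probes. Of 41 cell cycle genes 0 passed in limma over all genes or over the list alone, and Bub1b, a spindle checkpoint kinase, stood at −0.56 ± 0.15. The cell cycle median was −0.11 (camera adjusted p = 0.00167, and adjusted p = 0.638 with an estimated correlation), and the direction turned without wtIDH1 sample 1 (0.044, adjusted p = 0.705). It was −0.26 without wtIDH1 sample 2, −0.20 without mutIDH1 sample 1 and −0.048 without mutIDH1 sample 2.

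Lists tied to the IDH reaction itself did not pass. Of 32 IDH, citric acid cycle and 2-hydroxyglutarate enzymes 0 passed over all genes in limma, while 1 rose and 1 fell adjusted over the list alone (median −0.061, camera adjusted p = 0.114, or 0.0458 without mutIDH1 sample 1); Bcat1, a branched-chain aminotransferase, stood at 0.58 ± 0.11 (adjusted p = 0.0896). Of 21 chromatin enzymes that use 2-oxoglutarate and DNA methyltransferases 0 passed in limma (median −0.028, camera adjusted p = 0.379), with Kdm3a at −0.50 ± 0.12 (adjusted p = 0.134). Of 24 p53 targets 0 passed in limma (median 0.067, camera adjusted p = 0.292), with Cdkn1a at −0.38 ± 0.15. Cholesterol synthesis genes (18 measured, median −0.060, mean 0.0017, camera pointing lower at an adjusted p of 0.543) did not pass, and their median turned to 0.057 without mutIDH1 sample 2 and 0.090 without wtIDH1 sample 1. Among 26 immediate-early and heat-shock genes (median 0.044, camera adjusted p = 0.460), Ier3 fell by 1.47 ± 0.18, and 2 fell and 2 rose adjusted over the list alone.

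Because 4 of the genes with the steepest falls, Skap2, Hoxa2, Hoxa5 and Hoxa7, lie in 1 stretch of the RefSeq gene order, with Hoxa3, Hoxa4 and Hoxa6 between them, the genes in and around it were read out too, a choice made after the values were seen. Hoxa4 also fell (at least 3.15-fold higher in wtIDH1, adjusted p = 0.0200), while Hoxa3, Hoxa6 and Hoxa9 were at or under background in all samples. Hoxa13 was just above background in all 5 samples and stood at 0.14 ± 0.11 (adjusted p = 0.669). Of the genes further out, Snx10 stood at −0.025, Cbx3 at 0.26, Hnrnpa2b1 at −0.094, Hibadh at 0.27, Tax1bp1 at −0.15 and Jazf1 at 0.15, none of which passed.

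**Figure D3:**
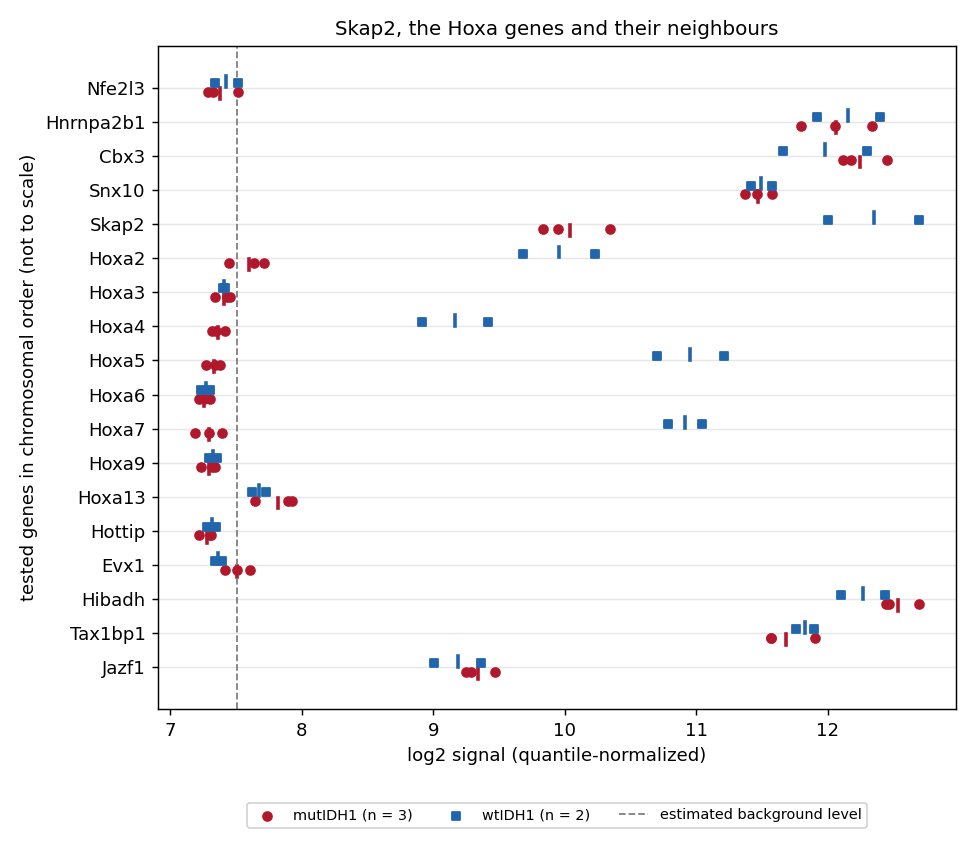
Log2 signal of the tested genes around Skap2 and the Hoxa genes in RefSeq gene order (vertical axis, not to scale) in the 3 mutIDH1 samples (red circles) and the 2 wtIDH1 samples (blue squares); short bars are group means and the dashed line is the background level of 7.51. Skap2, Hoxa2, Hoxa4, Hoxa5 and Hoxa7 are separated between the groups, whereas Snx10, on the other side of Skap2, has overlapping groups near 11.5.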

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

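Normexp on the matrix values, both stricter dim-probe filters, centring on genes above background, cyclic loess and the sex covariate were chosen after the data were seen. The counts of changed genes and of lists stayed within 1.5 times those of the main test under no dim-probe filter (244 genes), the mean of probes (196), normexp (258), the stricter filters (219 and 224), centring (236) and cyclic loess (204), and each of these shared at least 167 of the 228 genes. The count moved to 363 genes, 253 lower, with trended and robust moderation (206 shared), to 59, 10 higher and 49 lower, with sex as a covariate (55 shared), to 531, 202 higher and 329 lower, at an adjusted p of 0.10, and to 95, 17 higher and 78 lower, at 2-fold or more. Array weights left 160 genes, 50 of them higher. The test without moderation called 0 genes, higher or lower, with 1985 at an unadjusted p under 0.05 against 2429 in limma. Testing every probe on its own called 1 list higher, and an estimated correlation in camera called 0 lists, lower or higher, where fry called 11.

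Leaving out 1 sample gave between 0 (without mutIDH1 sample 2 or 3) and 479 genes (without wtIDH1 sample 2), 0 to 245 higher and 0 to 234 lower, and 15 to 17 lists, 13 to 17 lower and 0 to 2 higher. With 1 wtIDH1 sample left, that sample was assumed to vary like the others. Among lists called in the main test, cell cycle alone turned its direction, to 0.044 without wtIDH1 sample 1; of lists not called, medians that turned without some sample include those of neurons, astrocytes, mature oligodendrocytes, microglia, MHC class I and cholesterol synthesis. Over all alternatives, named genes kept direction and side of the threshold in 2173 of their values, lost the call in 275 and gained it in 49. Only the 56 named genes called in the main test could lose a call, and the 2173 values include those of genes that stayed uncalled. Of the called genes 0 turned direction. The cause was not tested.

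With the sample number as a block, limma called 0 genes, 0 higher and 0 lower (1562 at an unadjusted p under 0.05), and camera 18 lists, 2 of them higher. The samples were taken as separate tumours, not as pairs by number. Deviations from the group means correlated at −0.26 for number 1 and 0.11 for number 2. With 2 wtIDH1 samples these deviations mirror each other, so the correlations cannot decide whether equal numbers share an origin. Both number 1 samples were female and both number 2 samples male by Xist and Eif2s3y. The block leaves mutIDH1 sample 3 unpaired, and its changes equal those without that sample (Hoxa4 −1.80 in both), where limma also called 0 genes. Settings planned on the non-normalized table (neqc, quantile without background correction, normexp with scaling, detection p at 0.05 or 0.01) were not run, because its columns could not be tied to samples. Signal over background limits what can be seen of 5020 genes that lay at or under the background level on all arrays.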

Other observations

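Of the tests below, the one on forebrain transcription factors and those on other splits of the samples were chosen before their results were seen, and the others after; the genes and families in the first paragraph were chosen after their values were seen. Outside the lists, 4 transcription factor genes that rose in mutIDH1 gliomas were Sox21, Rfx4, Gsx1 and Pou3f1. Sox21 rose by 0.99 ± 0.09, Rfx4 by 1.34 ± 0.16, Gsx1, a patterning gene of the ventral forebrain, by 1.34 ± 0.18, and Pou3f1 by 0.99 ± 0.12 (log2, SE; limma adjusted p between 0.0216 and 0.0432). With the mean of the probes Sox21 gave 0.51 and still passed, and Rfx4 gave 0.37 and lost its call. Gsx1 lost its call with cyclic loess, and with sex as a covariate Rfx4, Gsx1 and Pou3f1 lost theirs at changes of 1.31, 1.28 and 0.99. Of 19 SOX genes 2 rose (Sox2 and Sox21) and 0 fell (3 rose under normexp and under centring, 2 under cyclic loess and with sex as a covariate). The 16 SOX genes above background on at least 1 array had a median change of −0.0098. Wnt7a, a secreted signal of neural tissue and brain vessels, rose by 1.02 ± 0.11, and Timp4, an inhibitor of matrix metalloproteinases, by 1.08 ± 0.10. In the other direction, 5 of 19 matrix metalloproteinases fell (Mmp2, Mmp3, Mmp9, Mmp10 and Mmp13) and 0 rose, a count kept under normexp, centring and cyclic loess, and 3 with sex as a covariate. Of 38 collagens 9 fell and 0 rose (10 under normexp, 7 under cyclic loess, 6 with sex as a covariate). Of 16 measured members of the MS4A family of membrane proteins, 3 lay above background on at least 1 array. Of the family 2 fell, Ms4a7 and Ms4a6d (−1.62 ± 0.14), and so did the osteoclast protease Ctsk (−1.55 ± 0.11). Ms4a7 lost its call with sex as a covariate. All of these calls were lost without mutIDH1 sample 2 or 3, where 0 genes passed in limma (1747 and 1849 at an unadjusted p under 0.05).

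Skap2, Hoxa2, Hoxa4, Hoxa5 and Hoxa7, which lie in 1 chromosome region, and En1, elsewhere in the genome, were lower in mutIDH1. A probe that binds another transcript is argued against for Hoxa2 and En1, where 2 of 2 second probes were also higher in both wtIDH1 samples, and stays open for the 4 genes with only 1 probe. A gain of the whole chromosome region in the wtIDH1 tumours is argued against by 6 expressed flanking genes, whose median change was 0.063 (from −0.15 to 0.27), while a gain of the Hoxa genes and Skap2 alone was not tested; Hoxa13, just above background, stood at 0.14 ± 0.11. A more rostral origin or identity of the mutIDH1 tumours is a hypothesis that the arrays could not decide: 7 of 14 measured forebrain transcription factors were above background, with a median change of 0.054 and 5 higher in mutIDH1, but wtIDH1 sample 2 had the highest score (0.27, against −0.36 in wtIDH1 sample 1). The form of IDH1 and the site of the tumours, which the labels do not give, stay open.

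The matrix, endothelial and mural lists were lower in mutIDH1 by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.0561, 0.174 and 0.116). A lower share of tumour cells in the wtIDH1 samples would raise markers of all other cell types alike. Mural (mean −0.55), monocyte and macrophage (−0.61), neutrophil (−0.33) and red blood cell lists (−0.91) moved with the endothelial list (−0.60). Microglia (−0.14), neuron (0.47), astrocyte (0.33), mature oligodendrocyte (0.12) and ependymal lists (0.059) did not pass. Each of these had scores of opposite sign in the 2 wtIDH1 samples (neuron −1.33 and 0.77), so they cannot decide. T and NK, B and dendritic cell lists (−0.029, −0.038 and −0.019) had many genes at background. The endothelial minus the microglia score differed by −0.46 between the groups (pooled SD 0.18) and was lower in every mutIDH1 sample. Without wtIDH1 sample 1 the score differed by −0.32, and the microglia median was −0.33, lower like the endothelial list. The microglia list was also picked after the values were seen, so the score cannot decide, and that share stays open. A single wtIDH1 tumour setting the shift is argued against by the matrix median, which stayed at −0.76 or lower without either wtIDH1 sample. A difference of vessels and matrix themselves with the form of IDH1, tumour site or stage, array batches and the grouping of so few samples all stay open.

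The T and NK cell list did not pass, while the monocyte and macrophage list was lower by camera at its preset correlation, with 6 of 34 members passing, but not with an estimated correlation (adjusted p = 0.139); the difference between the lists was not tested. Of the T and NK cell genes 61.3% lay at or under background on all arrays, against 20.6% of the monocyte and macrophage genes, so low signal is a candidate explanation for the absence of a call. The 12 T and NK cell genes above background had a median change of 0.026 (from −0.74 to 0.20). Whether T cell numbers differed is not decided by these values.

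The 5 samples can be divided into groups of 3 and 2 in only 10 ways, too few for a share under 0.05. The real division gave 228 changed genes, which 1 of the 10 reached, and the highest of the others gave 1. For lists, the real division gave 16, and 2 of the 10 gave as many. The highest of the others, with mutIDH1 samples 1 and 2 set apart, gave 18. It keeps both wtIDH1 samples together, as do those with mutIDH1 samples 1 and 3 (15 lists) or 2 and 3 (14 lists) set apart. Such divisions carry part of the real contrast. Those that separated the wtIDH1 samples called between 5 and 11 lists. The mean change of the matrix list was −0.77 in the real division and at most 0.54 in size in the others, and that of the interferon list was −0.29 and at most 0.31. Of the 9 other divisions, 3 called the matrix list and 6 the interferon list.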
